A study of Mus musculus with 12 samples.

How the data were processed

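Gene expression was measured by RNA sequencing of whole mouse corneas. There were 12 libraries in 4 groups of 3, and per the labels' protocols each library pooled 6 corneas from 3 mice. Control corneas had no injury and no treatment. Vehicle corneas were injured with benzalkonium chloride (BAK, named in full in the series title) and are described in the labels as having no treatment; whether they received any drops after BAK is not given in the sources used here. UCS and UCPRP corneas were injured in the same way and given one of a pair of biologics that the series title describes only as derived from cord blood; the labels do not expand the abbreviations. Per the labels' protocols, 5 µl of 0.2% BAK was given to each eye daily for 14 days, and 5 µl of 20% UCS or UCPRP was given 3 times daily for 10 days. Whether the days of treatment followed the days of BAK or overlapped with them is not given in the sources used here, so a difference between a treated group and Vehicle does not separate less injury from more repair. The time of harvest is not given in the sources used here.

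Per the labels' protocols, total RNA was extracted with the Qiagen RNeasy kit and libraries were made with the TruSeq Stranded Total RNA kit. The submitters' processing notes name HISAT and the genome build GRCm38 without version. The counting tool, the annotation and the use of strand are not given in the sources used here. The deposited values are estimated counts per gene and library, named read counts per the file headers; they have 2 decimals, 64.9% of them were whole numbers, and they were not scaled to library size. Because reads were divided between features, values of near-identical genes, and of genes that overlap on opposite strands, are uncertain. The table held 19702 genes by Entrez identifier and symbol, of which 19644 matched the RefSeq annotation of GRCm38.p6 (19497 of them protein-coding) and 58 did not; coordinates come from that annotation.

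Library totals ran from 18.55 M (UCS replicate 2) to 20.44 M estimated counts (Control replicate 2). A count of 3, the limit that a count of 0 allows, corresponded to 0.147 to 0.162 counts per 1 M counts (CPM), which covers counting error only. Correlations of log2 CPM between libraries of a group ran from 0.96 to 0.986, and counts differed between libraries of a group by at least 18.3 times the variance that counting error gives (chi-square per degree of freedom). The common biological coefficient of variation was 0.227, and the median standard error of a log2 fold change was 0.171 to 0.172 in the 6 comparisons. For genes, the standard error (SE) is the absolute log2 fold change divided by the square root of edgeR's F statistic. It is thus implied by the test and is no direct measure of the spread between libraries.

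Counts were filtered with filterByExpr (minimum count 10), which left 16124 genes, scaled with TMM (factors from 0.825 to 1.067) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion and 1 term per group over all 12 libraries. The 6 pairwise comparisons of the 4 groups were tested, each with Benjamini-Hochberg adjustment over the genes, and a gene was called at an adjusted p under 0.05. A gene with 0 counts in every library of a group has its fold given as a lower bound against 3 counts per library, and a gene with 1 to 3 counts has a ratio of total counts with its 95% interval; these bounds and intervals cover counting error only. CPM values are means ± SD over 3 libraries.

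Gene groups were 42 lists with 745 symbols, of which 716 were found in the table (12 of them by a synonym). They cover immune cells and mediators, corneal and conjunctival epithelium, stroma and matrix, nerve, vessel, cell state, and other tissues or technical signals; the mitochondrial list had no measured gene, which left 41. Each was tested against all other genes with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, with adjustment over the 41 lists of a comparison. No list call in any of the 6 comparisons held when camera estimated the correlation between genes, and that p is given where called lists are described. The fry test, which asks whether a list's genes move one way on balance and compares them with no other genes, was run beside it. Members past the gene test are counted over all genes and also adjusted over the list alone.

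The genes named were set by rule. For each of the 3 comparisons Vehicle with Control, UCS with Vehicle and UCPRP with Vehicle they were the 5 largest changes each way among called genes with a mean of at least 5 CPM and no overlap between the replicates of the 2 groups (leaving out Gm, Rik and bare identifiers), a fixed set of genes that included Krt12, Pax6, Krt10, Il1b, Il6, Tnf, Mmp9, S100a8, Muc5ac, Gap43 and Tubb3, and up to 4 members per list (the largest changes past the test, otherwise the member with the highest mean CPM). For the other 3 comparisons they were the 3 largest each way and the members of called lists. Where no gene passed, the 3 smallest p were taken. Dbp, Arntl, Krt4, Krt14, Epcam, Perp, and Krt5 and Krt13 in the comparison of Vehicle with Control, were named after their values were seen.

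The share of genes called in Vehicle against Control whose treatment change had the opposite sign was set beside 20 simulated data sets, because both comparisons use the same Vehicle libraries. Counts were drawn from negative binomial distributions with each gene's dispersion, once with all groups unchanged and once with a real injury and a treatment without effect. Each gene was drawn independently, so variation that the genes of a library share was not simulated. With 3 Vehicle libraries, they could not be divided into parts of at least 2.

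The lists, the rule for named genes, the tests and 10 alternatives were fixed before the data were examined: RLE scaling as in DESeq2, upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, fitting only the 2 groups compared, a log2 fold change of at least 1, a replicate block, and removal of haemoglobin, mitochondrial and ribosomal RNA genes before scaling. Each of the 12 libraries was also left out in turn, and list tests were repeated with an estimated correlation and with fry. A further 5 alternatives were chosen after seeing the data: the retina list as a covariate, the retina, lens and muscle lists as covariates, clock phase as a term, and fits within each phase. Clock phase divides the libraries by a score of circadian genes (Per1, Per2, Per3, Dbp, Tef, Nr1d1, Nr1d2 and Ciart minus Arntl, Npas2 and Clock), with a gap of 2.19 on the log2 scale between 8 high-clock and 4 low-clock libraries. The injury score, also chosen after seeing the data, is the mean log2 CPM of the 724 genes called higher, minus that of the 597 genes called lower, in both UCS and UCPRP against Control (1321 in all), set to 0 at the Control mean. Vehicle was in neither of these comparisons, though its libraries entered the filter and the dispersion of the fit.

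The scripts were tested on simulated counts. In the simulation of UCS with Vehicle, 92.4% of genes changed 4-fold, 56.7% of genes changed 2-fold and 9% of genes changed 1.5-fold were called, and for UCPRP with Vehicle these shares were 93.9%, 56.7% and 13.4%. For Vehicle with Control they were 92.4%, 59.7% and 14.9%. For UCPRP with UCS they were 87.9%, 58.2% and 9%. Between 3 and 11 unchanged genes were called per comparison. The changed genes were drawn at random, so the shares recovered are averages over genes. They do not apply to the genes that vary most between libraries. A list of 20 genes raised by 0.5 was called and none of 40 unchanged lists was. Genes were drawn independently there, so this gives no rate of false list calls for genes that vary together. In the real libraries, splits that mixed the groups called up to 21 of 41 lists. Such splits keep part of any real group difference, so this is no rate of false calls either.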

Results

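The data were RNA-seq profiles of 12 pools of whole mouse corneas, with 3 pools in each of 4 groups: uninjured Control, BAK-injured Vehicle, and BAK-injured corneas given UCS or UCPRP. Each library held RNA from 6 corneas of 3 mice, so the replicates are pools and not single animals. Library totals ran from 18.55 M to 20.44 M estimated counts with a median of 19.025 M, and between 17426 and 17867 genes were detected per library. The first principal component of log2 CPM held 39.4% of the variance and the second held 21.1%. Fold changes and adjusted p values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16124 genes, and n is 3 libraries per group throughout.

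A pair of measured features varied within the groups. Circadian genes divided the libraries into 8 with high Dbp (139 to 280 CPM) and low Arntl (9.12 to 24.4 CPM), and 4 with low Dbp (14.7 to 25.9 CPM) and high Arntl (39.1 to 66.4 CPM). The low-clock libraries were Control replicate 3, Vehicle replicates 1 and 2, and UCS replicate 1, so Vehicle had 1 high-clock library and UCPRP had only high-clock ones. Transcripts of neighbouring tissue also varied between libraries. Genes of the retina list took 0.273% to 1.67% of counts, and Cryaa, a lens crystallin, took 0.00135% to 1.52%.

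The comparison of Vehicle with Control asks what BAK did to the cornea. Several transcripts of the mature corneal epithelium were nearly lost, Krt12, Slurp1 and Lypd2 among them. Krt12 (Entrez 268482, chromosome 11, 99415664 to 99422593), the keratin of differentiated corneal epithelial cells, fell from 22550 ± 9050 CPM in Control to 13.43 ± 9.15 CPM in Vehicle (log2 fold change −10.71, SE 1.71, adjusted p = 0.00142 by edgeR). Slurp1 and Lypd2, secreted and membrane-bound Ly6-type proteins of surface epithelium, fell from 1513 ± 531 and 1698 ± 579 CPM to below 1 CPM (log2 fold changes −11.27 and −11.74). Aldh3a1, the abundant aldehyde dehydrogenase of the corneal epithelium, fell from 11410 ± 5460 to 1019 ± 426 CPM (log2 fold change −3.49). Pax6, the transcription factor of eye development, fell from 655.6 ± 43.4 to 422 ± 36 CPM (log2 fold change −0.64, SE 0.13). Of the 18 tested genes of the corneal epithelium list 11 fell and 2 rose, or 12 and 2 adjusted over the list alone (camera adjusted p = 4.59e-05; adjusted p = 0.33 with an estimated correlation). Among the 2 that rose was Muc16, a membrane mucin of the ocular surface, with 0 counts in Control and at least 39-fold more in Vehicle. Ppp1r3c, a glycogen-targeting subunit of protein phosphatase, and Fam83a, both in no list, also fell (log2 fold changes −5.50 and −4.94).

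Genes of cell junctions fell with them. Of 20 tested junction genes 6 fell and none rose (11 fell adjusted over the list alone), with Dsg1a at a log2 fold change of −4.45 and Cgn, which encodes cingulin, at −0.90; reads of Dsg1a may be shared with its near-identical neighbours. The list was lower by camera (adjusted p = 0.000136; adjusted p = 0.586 with an estimated correlation). The epidermal keratinization list moved both ways, with 8 of 23 genes higher and 4 lower (11 and 5 adjusted over the list alone), and was not called by camera (adjusted p = 0.0954). Sprr3, a cornified envelope protein, was at least 22.6-fold higher, while Cdsn, which encodes corneodesmosin, fell with a log2 fold change of −3.86. Krt10, the keratin of suprabasal epidermis, rose from 10.37 ± 1.71 to 23.56 ± 9.54 CPM (log2 fold change 1.18, edgeR adjusted p = 0.0262), but lost its call without Control replicate 1, Control replicate 3 or Vehicle replicate 3, and its adjusted p reached 0.0966 over the alternatives. Of 8 limbal progenitor genes 3 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.134), with Gpha2 rising from 41.71 ± 7.9 to 123.2 ± 4.42 CPM and Abcg2 falling from 28.79 ± 5.25 to 14.5 ± 1.68 CPM.

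Mucin and goblet cell genes appeared in the injured corneas. Muc5ac, the main secreted mucin of conjunctival goblet cells, rose from 1.23 ± 0.989 to 543.5 ± 101 CPM (log2 fold change 8.77, SE 0.57, edgeR adjusted p = 2.24e-05). The related mucin gene Muc5b rose with a log2 fold change of 8.86, Tff1, a trefoil factor secreted with mucin, with 7.85, and Agr2, an endoplasmic reticulum protein needed for mucin assembly, with 4.27. Gp2 rose from 0.4463 ± 0.447 to 222.8 ± 52.2 CPM (log2 fold change 8.93). In the conjunctiva and goblet cell list 11 of 14 genes rose and none fell, with the same counts adjusted over the list alone (camera adjusted p = 2.18e-10; adjusted p = 0.219 with an estimated correlation). The antimicrobial lectin gene Reg3g had 671 counts in Vehicle and 2 in Control, a ratio of 314 (95% interval 86.5 to 2600).

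Inflammatory genes rose. Il1b rose from 1.344 ± 0.686 to 72.61 ± 56.9 CPM (log2 fold change 5.76, SE 1.10, edgeR adjusted p = 0.00492), and Csf3, the granulocyte growth factor, rose with a log2 fold change of 5.11. By limma-voom Il1b had an adjusted p of 0.119. Il6 was too low to test, with 38 counts in Vehicle and 2 in Control (ratio 17.8, interval 4.59 to 152), and Tnf did not pass (22.65 ± 6.12 CPM in Control, 16.82 ± 6.78 CPM in Vehicle; edgeR adjusted p = 0.475). In the inflammatory cytokine and receptor list 16 of 25 genes rose and none fell, or 18 and 1 adjusted over the list alone (camera adjusted p = 1.81e-08; adjusted p = 0.313 with an estimated correlation). Of 26 chemokine genes 14 rose and none fell, or 15 adjusted over the list alone, among them the neutrophil attractant Cxcl5 (log2 fold change 4.91), and Cxcl17 (4.59; camera adjusted p = 1.09e-08 for the list, adjusted p = 0.251 with an estimated correlation). Ppbp, a platelet chemokine gene outside the list, rose from 1.624 ± 1.35 to 508.1 ± 150 CPM.

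Genes of myeloid cells rose in the same direction. In the neutrophil list 8 of 11 genes rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.33e-05; adjusted p = 0.326 with an estimated correlation). S100a8, a calcium-binding protein of neutrophils, rose from 0.3424 ± 0.0792 to 36.79 ± 26.6 CPM (edgeR adjusted p = 0.00144, limma-voom adjusted p = 0.075), and Csf3r, the receptor for the granulocyte growth factor, rose with a log2 fold change of 4.69. The macrophage and monocyte list had 17 of 21 genes higher and none lower, or 19 adjusted over the list alone (camera adjusted p = 1.03e-16; adjusted p = 0.196 with an estimated correlation). Within it Lyz2, the lysozyme of macrophages, rose from 86.08 ± 25.8 to 422.5 ± 54.1 CPM (log2 fold change 2.30, SE 0.27), and Cd14 and Ccr2 rose with log2 fold changes of 2.72 and 2.42. Of 17 genes of MHC class II and dendritic cells 11 rose, or 16 adjusted over the list alone, among them Clec9a (log2 fold change 2.55), Itgax (2.09) and Flt3 (1.77; camera adjusted p = 2.83e-08 for the list, adjusted p = 0.313 with an estimated correlation). Complement genes rose in 8 of 15 cases, or 11 adjusted over the list alone, with C5ar1 at 3.29, C3 at 2.18 and C3ar1 at 1.81 on the log2 scale (camera adjusted p = 2.78e-07; adjusted p = 0.196 with an estimated correlation).

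Interferon-stimulated genes went the other way. Of 19 tested 10 fell and none rose, or 11 adjusted over the list alone (camera adjusted p = 7.46e-06; adjusted p = 0.553 with an estimated correlation). Ifi27l2a fell from 79.12 ± 12.3 to 15.65 ± 1.51 CPM (log2 fold change −2.34, SE 0.20, edgeR adjusted p = 8.04e-05), and Isg15 fell from 130 ± 44.6 to 50.99 ± 7.32 CPM. Among lymphoid markers, no gene passed of 15 of T and NK cells, 14 of which had a higher mean (median 0.35, camera adjusted p = 0.0954), and 1 of 5 B and plasma cell genes rose, with the same counts adjusted over each list alone (camera adjusted p = 0.68).

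Matrix and matrix-cleaving enzymes rose. Tnc, the wound matrix protein tenascin C, rose from 13.53 ± 4.41 to 240 ± 41.1 CPM (log2 fold change 4.15, SE 0.51, edgeR adjusted p = 0.000338), and the collagen cross-linking enzyme Lox and the fibrillar collagen Col3a1 rose with log2 fold changes of 2.57 and 2.26. Of 23 genes of extracellular matrix and myofibroblasts 14 rose and none fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 2.83e-08; adjusted p = 0.313 with an estimated correlation). Among proteases and their inhibitors 14 of 21 rose and 1 fell, or 15 and 1 adjusted over the list alone, with Mmp13 (log2 fold change 5.53), Mmp9 (4.83; 1.273 ± 0.552 CPM in Control, 36.58 ± 18.4 CPM in Vehicle) and the inhibitor Timp1 (3.74; camera adjusted p = 1.81e-08 for the list, adjusted p = 0.196 with an estimated correlation). Vessel genes rose in 6 of 18 cases, also adjusted over the list alone, with the endothelial genes Cdh5 and Pecam1 at 1.13 and 1.08 on the log2 scale (camera adjusted p = 0.000213; adjusted p = 0.313 with an estimated correlation). The skeletal muscle list was higher in the same libraries (all of 14 genes, median 2 on the log2 scale, none past the test; camera adjusted p = 0.00361; adjusted p = 0.649 with an estimated correlation), a call lost without Control replicate 2 (adjusted p = 0.109). The keratocyte list did not move as a set: 1 of 11 genes rose (Lum, 1.05) and 1 fell (Kera, −1.45), or 1 and 2 adjusted over the list alone (camera adjusted p = 0.68). None of 8 corneal endothelium genes passed, also adjusted over the list alone (camera adjusted p = 0.747), and Col8a2 stood at 310.6 ± 24.3 CPM in Control and 310.5 ± 74.9 CPM in Vehicle.

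Nerve genes changed singly and not as sets. Ntf3, Artn and the receptor gene Ntrk2 fell with log2 fold changes of −1.47, −1.29 and −0.87. Piezo2, the mechanosensitive channel, fell from 51 ± 8.43 to 15.55 ± 0.779 CPM (log2 fold change −1.71, edgeR adjusted p = 0.000174). Gap43, the growth cone protein, rose with a log2 fold change of 1.08 (edgeR adjusted p = 0.0154), but lost its call without Control replicate 1, Control replicate 2 or Vehicle replicate 2, where its adjusted p reached 0.0574. Tubb3, the neuronal tubulin, was not called (log2 fold change 0.60, SE 0.37, edgeR adjusted p = 0.334), and was called with the retina list as a covariate (adjusted p = 0.0341). Of 45 axon guidance genes 5 rose and 2 fell (camera adjusted p = 0.68), with Ephb2 at 0.90 and Plxnd1 at 0.72 on the log2 scale. Of 23 neurotrophic genes 2 rose and 3 fell, or 2 and 7 adjusted over the list alone (camera adjusted p = 0.254). In the axon growth list 1 of 26 rose and 1 fell (camera adjusted p = 0.324), in the sensory neuron list 1 of 10 rose and 1 fell (camera adjusted p = 0.971; median log2 fold change 0.26, direction of the test down), and in the Schwann cell and myelin list 1 of 16 rose (camera adjusted p = 0.747; mean 0.04, median −0.04). For these 3 lists and for axon guidance the counts were the same adjusted over the list alone.

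In all, 1545 genes rose and 1116 fell in Vehicle against Control, 917 and 389 of them by at least 1 on the log2 scale, and 18 of 41 lists were called by camera. The count of lower genes was 626 without Vehicle replicate 2 and 604 when only these 2 groups were fitted. With clock phase as a term 2224 genes were called; within the high-clock libraries (1 Vehicle, 2 Control) 574 were called, and within the low-clock libraries (2 Vehicle, 1 Control) 154, with the spread of the group of 1 taken from other libraries. Of the 109 called genes that the naming rule gave, 75 stayed called in the same direction under each of the 20 settings run for named genes (8 alternatives and 12 fits with 1 library left out).

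**Figure D1:**
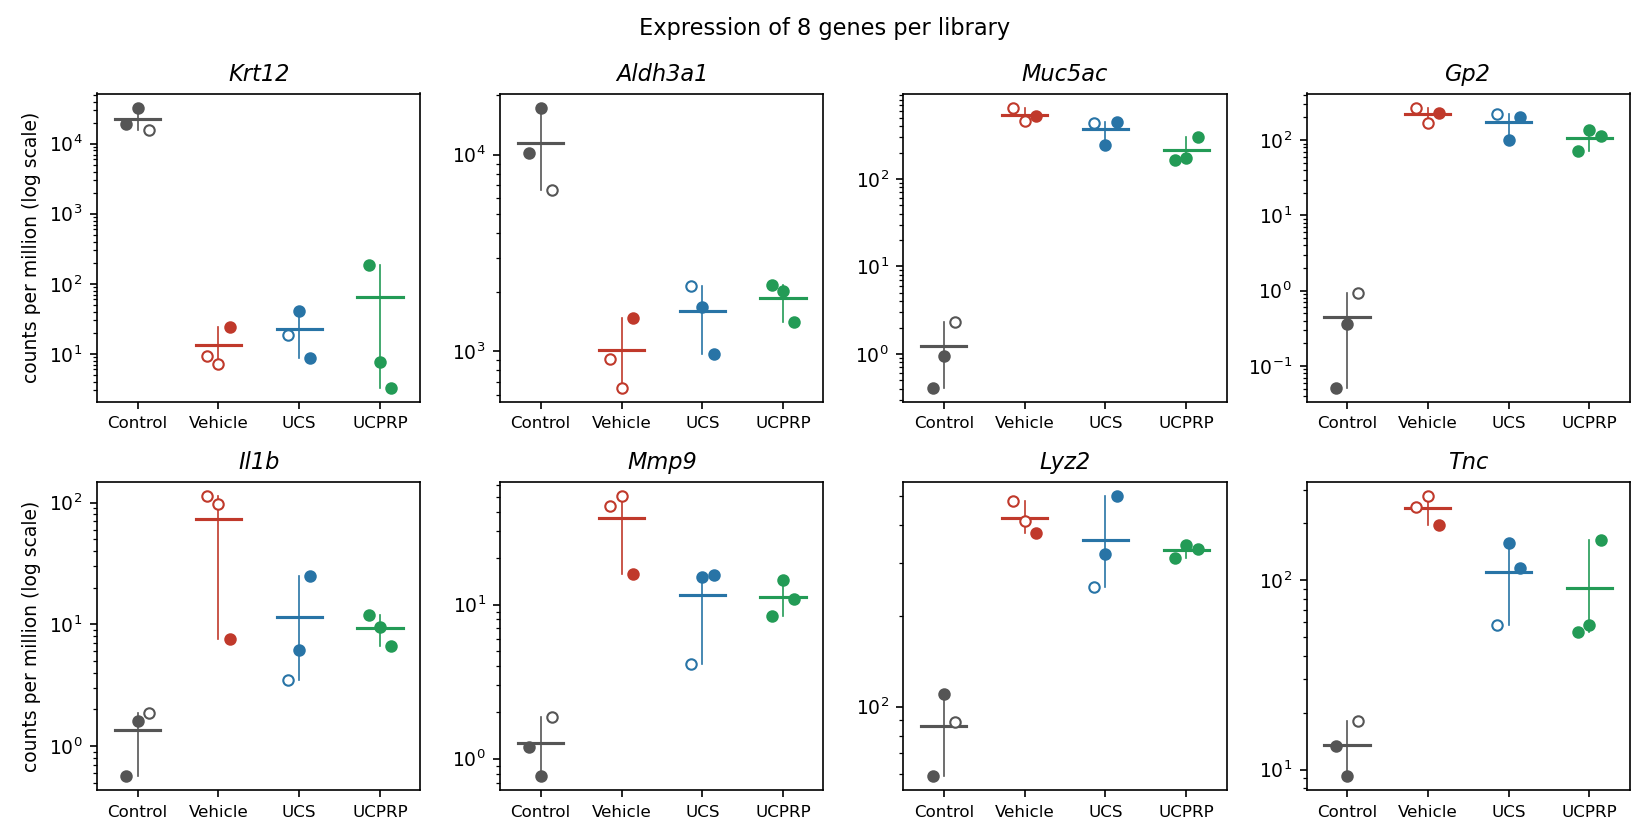
CPM (log axis) of 8 genes in each of the 12 libraries, by group; circles are libraries, filled for high-clock and open for low-clock ones, horizontal lines are group means and vertical lines run from the lowest to the highest library. Krt12 and Aldh3a1 lie lower, and Muc5ac, Gp2, Lyz2 and Tnc higher, in each injured library than in each Control library, while Il1b ran from 7.56 to 113 CPM within Vehicle.

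Whether UCS changed the injured cornea was asked by comparing UCS with Vehicle. The acute inflammatory transcripts had lower means in UCS than in Vehicle, but no gene passed the test. Il1b averaged 11.54 ± 11.7 CPM in UCS and 72.61 ± 56.9 CPM in Vehicle (log2 fold change −2.65, SE 0.90, edgeR adjusted p = 0.899), and S100a8 averaged 4.882 ± 4.69 and 36.79 ± 26.6 CPM (−2.91, SE 0.82). Mmp9 averaged 11.53 ± 6.45 and 36.58 ± 18.4 CPM (log2 fold change −1.66, SE 0.51), and Cxcl5 38.8 ± 13.4 and 166 ± 100 CPM (−2.10, SE 0.50). Krt12 stayed near its Vehicle level (22.62 ± 16.2 against 13.43 ± 9.15 CPM), as did Muc5ac (374.7 ± 114 against 543.5 ± 101 CPM; log2 fold change −0.54, SE 0.39).

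The genes ranked first were Snai1, a transcription factor of epithelial-mesenchymal transition (log2 fold change −0.69), Arl14 (−2.09) and Tgfb3 (−0.49), each with an edgeR adjusted p of 0.894. By edgeR 0 genes were called and 782 had an unadjusted p under 0.05, where chance alone gives 806. DESeq2 called 2 genes higher and 11 lower (Snai1, Tgfb3 and Cxcl5 among the genes named here), and limma-voom called 0. Sentinel genes of nerve and surface were near Vehicle: log2 fold changes were 0.34 for Pax6, −0.20 for Krt10, −0.33 for Tnf, −0.42 for Gap43 and −0.35 for Tubb3.

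As sets, 12 lists were lower and 4 higher in UCS than in Vehicle by camera. Of 23 matrix genes 21 had a lower mean (median log2 fold change −0.40; 8 passed adjusted over the list alone; camera adjusted p = 5.48e-10), as had 18 of 21 protease genes (median −0.59; 8 passed adjusted over the list alone; camera adjusted p = 6.61e-10). The inflammatory list (median −0.38, none passed adjusted over the list alone), the macrophage list (−0.33, 4 passed) and the neutrophil list (−1.47, 4 passed) had camera adjusted p values of 3.66e-08, 3.66e-08 and 8.83e-07, and chemokines (−0.68, 1 passed) 5.79e-06. The vessel list was lower as well (median −0.27, 1 passed adjusted over the list alone; camera adjusted p = 1.24e-05). With an estimated correlation none of these was called: adjusted p = 0.221 with an estimated correlation for proteases and 0.404 for the other 6. Cell cycle genes were lower (median −0.38, camera adjusted p = 6.27e-06; adjusted p = 0.719 with an estimated correlation) but not past the threshold without Vehicle replicate 1 (adjusted p = 0.201). Their list mean was 5.37, 5.2 and 4.27 in Vehicle replicates 1, 2 and 3, and 4.51, 4.44 and 4.92 in UCS replicates 1, 2 and 3. The corneal epithelium list was higher (median 0.23, camera adjusted p = 0.00771; adjusted p = 0.719 with an estimated correlation), as was the junction list (0.17, 0.00777; adjusted p = 0.75 with an estimated correlation); the first lost its call without Vehicle replicate 2, and the second without Vehicle replicate 2, Vehicle replicate 3 or UCS replicate 1, with adjusted p values up to 0.167 and 0.196. The skeletal muscle list moved with them (median −1.89, camera adjusted p = 3.84e-05; adjusted p = 0.719 with an estimated correlation), and so did the circadian list (0.43, 0.0103; adjusted p = 0.696 with an estimated correlation). The first lost its call without Vehicle replicate 3 (adjusted p = 0.0514), and the second without Vehicle replicate 1, UCS replicate 2 or UCS replicate 3 (up to 0.247).

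Clock phase ran alongside these differences. In the low-clock libraries Il1b was at 113 and 97.1 CPM in Vehicle and at 3.51 CPM in UCS; in the high-clock libraries it was at 7.56 CPM in Vehicle and at 6.21 and 24.9 CPM in UCS. With phase as a term edgeR called 0 genes (637 at an unadjusted p under 0.05) and camera called 14 lists. Within either phase 0 genes were called, but 1 of the 2 groups then held 1 library, with the spread taken from other libraries of that phase, so these fits say little. Without Vehicle replicate 3, the one high-clock library of that group, 2 genes were called higher and 35 lower, Cxcl5 among them.

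The comparison of UCPRP with Vehicle asks the same of the other biologic. The same inflammatory genes had lower means, again with none past the test. Il1b averaged 9.357 ± 2.63 CPM in UCPRP against 72.61 ± 56.9 CPM in Vehicle (log2 fold change −2.96, SE 0.92, edgeR adjusted p = 0.359). S100a8 averaged 5.485 ± 2.68 CPM (−2.75, SE 0.81), Mmp9 11.25 ± 2.99 CPM (−1.70, SE 0.51) and Cxcl5 32.66 ± 6.48 CPM (−2.35, SE 0.51). Muc5ac averaged 213.5 ± 78 CPM, against 543.5 ± 101 CPM in Vehicle (log2 fold change −1.35, SE 0.40, edgeR adjusted p = 0.359), and Ltf, the neutrophil and tear protein lactoferrin, 300.2 ± 92.7 against 829.4 ± 143 CPM (edgeR adjusted p = 0.373). Il6 had 1 count in UCPRP and 38 in Vehicle (ratio 36.9, interval 6.23 to 1490), all of the latter in the low-clock Vehicle replicates 1 and 2, with 0 in the high-clock replicate 3. Krt12 was at 186 CPM in UCPRP replicate 1 and at 7.55 and 3.29 CPM in the other UCPRP libraries.

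The genes ranked first were Arl14 (log2 fold change −2.64), the chemokine gene Ccl12 (−1.66), whose reads may be shared with related chemokine genes, and Avp, which encodes vasopressin (1 count in UCPRP, 48 in Vehicle; ratio 46.6, interval 7.97 to 1880), each with an edgeR adjusted p of 0.331. By edgeR 0 genes were called and 1572 had an unadjusted p under 0.05. DESeq2 called 6 genes higher and 139 lower, and limma-voom called 0. The log2 fold changes of the other sentinel genes were 0.19 for Pax6, −0.49 for Krt10, −0.20 for Tnf, −0.15 for Gap43 and 0.47 for Tubb3.

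By camera 18 lists were lower and 2 higher in UCPRP than in Vehicle. Lower means were found for 20 of 21 macrophage genes (median log2 fold change −0.58; 13 passed adjusted over the list alone; camera adjusted p = 1.21e-13) and 23 of 25 inflammatory genes (−0.80; 8 passed; camera adjusted p = 2.58e-09). Proteases (median −0.78, 8 passed adjusted over the list alone), chemokines (−1.25, 11 passed and 1 passed in the other direction) and neutrophil genes (−2.24, 8 passed) had camera adjusted p values of 4.52e-08, 1.36e-07 and 8.99e-07, and vessel genes (−0.31, 2 passed) 6.42e-05. For each of these 6 lists the adjusted p = 0.351 with an estimated correlation. Each of 19 interferon-stimulated genes had a lower mean (median −0.46, camera adjusted p = 1.37e-08; adjusted p = 0.388 with an estimated correlation), as had each of 25 cell cycle genes (−0.60, 4.52e-08; adjusted p = 0.532 with an estimated correlation). The cell cycle list mean was 5.37 and 5.2 in the low-clock Vehicle libraries and 4.27 in the high-clock one. In the UCPRP libraries, all high-clock, it was 4.6, 4.52 and 4.23. The cell death list (−0.36, 5.68e-06) and the complement list (−0.25, 0.00205) were lower, both with an adjusted p = 0.388 with an estimated correlation. Matrix genes were lower too (−0.19, 6 passed adjusted over the list alone, camera adjusted p = 0.000265; adjusted p = 0.532 with an estimated correlation), though not past the threshold without Vehicle replicate 3 (adjusted p = 0.225). Circadian genes moved with them (median 0.60, camera adjusted p = 0.00124; adjusted p = 0.388 with an estimated correlation), as did skeletal muscle genes (−1.06, 0.000569; adjusted p = 0.625 with an estimated correlation), which lost the call without Vehicle replicate 3 or UCPRP replicate 3 (adjusted p up to 0.516).

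Within the high-clock libraries, where Vehicle had 1 library and UCPRP 3, edgeR called 0 genes (272 at an unadjusted p under 0.05), with no spread measurable within Vehicle, and Il1b was at 7.56 CPM in Vehicle and at 11.9, 9.45 and 6.68 CPM in UCPRP. With phase as a term edgeR called 0 genes (745 at an unadjusted p under 0.05) and camera called 17 lists. Without Vehicle replicate 3, 19 genes were called higher and 176 lower, Il1b (adjusted p = 0.0411) among them.

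Among the 2661 genes that the injury changed, the treatment change had the opposite sign to the injury change for 2111 (79.3%) in UCS and 2168 (81.5%) in UCPRP, though edgeR called 0 of these treatment changes. Both changes use the same Vehicle libraries, which alone gives opposite signs: in 20 simulations with a real injury and no treatment effect the share was 62.4% on average, between 59.9% and 64.2% for UCS and between 59.5% and 64.4% for UCPRP. With all groups unchanged it was 66.7% for UCS (up to 68%) and 67.1% for UCPRP (up to 69.2%) over the same 2661 genes. The covariance of the paired log2 fold changes was −0.661 for UCS and −0.894 for UCPRP, against a simulated mean of −0.163 for each. Because genes were simulated independently, neither the shares nor the covariances separate a treatment effect from variation that genes of a Vehicle library share. When the 6 injured libraries of a pair of groups were assigned anew in the 20 possible ways, the highest share other than the real one was 80.8% for UCS, above its real share, and 77.3% for UCPRP. With clock phase as a term the shares were 77.9% and 80.2%. When 1 Vehicle library gave the injury change and the others the treatment change, they were 65.7%, 82.4% and 66.8% for UCS and 84.9%, 82.2% and 70% for UCPRP. That division was not simulated, and the simulated shares above, with shared Vehicle libraries, are no measure for it.

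The changes from Vehicle in the 2 treated groups resembled each other across genes, with r = 0.705 over 16124 genes, which are not independent replicates, against 0.495 in simulations of unchanged groups that share the Vehicle libraries. The covariance was 0.121 against a simulated 0.0596, and 70.1% of genes had the same sign against a simulated 66.4%. Genes were drawn independently in these simulations. Variation shared by the genes of a Vehicle library, such as that of clock phase, was not in them, so the excess does not show a common treatment response. An injury score per library, chosen after seeing the data, was 3.06 ± 0.10 in Vehicle, 2.83 ± 0.20 in UCS and 2.73 ± 0.07 in UCPRP, with Control at 0 ± 0.24. Vehicle lay 0.28 above the 6 treated libraries (two-sided permutation p = 0.0357 over 84 assignments, and 0.0476 adjusted over 2 measures). The genes of the score were chosen by the labels of the treated libraries and held fixed in the permutation. That p is therefore approximate, and it takes no account of clock phase. The mean of the inflammatory list was 4.21 ± 0.67 in Vehicle, 3.56 ± 0.24 in UCS and 3.4 ± 0.15 in UCPRP, a difference of 0.73 (exact two-sided permutation p = 0.0476). This test of 1 of the 41 lists was not among the tests fixed before the data were examined. Its p takes no account of the choice of list. With clock phase as a term, treated minus Vehicle in the inflammatory list mean was −0.48 (SE 0.26). In the high-clock libraries that mean was 3.48 in Vehicle, 3.32 and 3.8 in UCS, and 3.57, 3.32 and 3.29 in UCPRP, and in the low-clock libraries it was 4.8 and 4.35 in Vehicle and 3.56 in UCS. Within the high-clock libraries the injury score was 2.96 in Vehicle, 2.8 and 3.05 in UCS, and 2.66, 2.75 and 2.79 in UCPRP; within the low-clock libraries it was 3.15 and 3.07 in Vehicle and 2.64 in UCS, and each phase held too few libraries for a test.

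**Figure D2:**
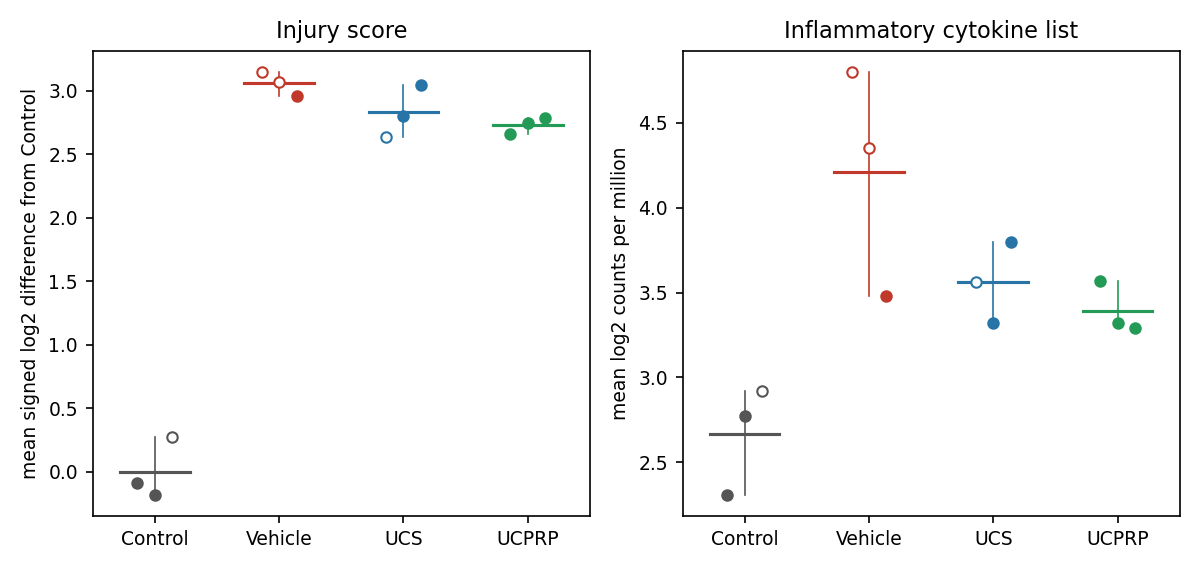
Injury score (left, log2 scale, Control mean at 0) and mean of the inflammatory list (right, log2 CPM) for each library by group, drawn with the same symbols and lines as the plot of 8 genes. Vehicle libraries score 2.96 to 3.15 and treated libraries 2.64 to 3.05.

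The treated corneas remained far from Control. Against Control 1032 genes were higher and 721 lower in UCS, and 854 and 817 in UCPRP (edgeR); 933 of the higher and 652 of the lower genes in UCS were also called in that direction in Vehicle, where independent lists would share 98.9 and 49.9. For UCPRP 775 and 656 were shared with Vehicle, against 81.8 and 56.5 for independent lists, and part of each overlap may come from the shared Control libraries. Krt12 was lower with log2 fold changes of −9.96 and −8.43 in the 2 groups (edgeR adjusted p = 0.00284 and 0.00592), Slurp1 with −11.98 and −9.55, and Aldh3a1 with −2.83 and −2.61. Muc5ac was higher with log2 fold changes of 8.24 and 7.43, Gp2 with 8.57 and 7.87, and Muc16 was at least 37.3-fold and 19.2-fold higher. The matrix genes Tnc (3.03 and 2.75) and Thbs2 (1.47 and 1.75), the macrophage gene Lyz2 (2.05 and 1.94) and the inflammasome gene Casp1 (2.66 and 2.29) also stayed up. Mmp9 stood at 3.16 and 3.13 on the log2 scale (edgeR adjusted p = 0.00555 and 0.00668), calls that limma-voom did not make (adjusted p = 0.105 and 0.0854). Of the named genes called here, 39 of 61 in UCS and 33 of 58 in UCPRP stayed called under each setting run for named genes, which did not include fits within a phase.

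Set tests against Control gave 18 lists for UCS and 15 for UCPRP. Goblet cell genes rose in 11 of 14 cases in both groups, also adjusted over the list alone (camera adjusted p = 3.59e-13 and 1.96e-11; adjusted p = 0.212 and 0.389 with an estimated correlation). Macrophage genes rose in 13 and 12 of 21 cases, or 17 and 14 adjusted over the list alone (camera adjusted p = 1.36e-14 and 4.98e-10; adjusted p = 0.212 and 0.389 with an estimated correlation). Inflammatory genes rose in 9 and 5 of 25 cases, or 13 and 8 adjusted over the list alone (camera adjusted p = 3.72e-05 and 0.00229; adjusted p = 0.569 and 0.772 with an estimated correlation). Corneal epithelium genes fell in 9 and 11 of 18 cases, and 11 in each adjusted over the list alone (camera adjusted p = 0.00044 and 7.85e-06; adjusted p = 0.557 and 0.452 with an estimated correlation). Interferon-stimulated genes fell in 11 and 12 of 19 cases, or 12 and 16 adjusted over the list alone, with Ifi27l2a at −2.42 and −2.62 and Rsad2 at −2.03 and −2.54 on the log2 scale (camera adjusted p = 7.16e-09 and 4.06e-14; adjusted p = 0.471 and 0.389 with an estimated correlation). With clock phase as a term 1693 genes were called for UCS and 1432 for UCPRP, and 1027 and 1009 within the high-clock libraries. The counts of higher genes fell to 655 for UCS and 513 for UCPRP without Control replicate 1.

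The direct comparison of UCPRP with UCS asks whether the biologics differed. Il1b stood at 9.357 ± 2.63 CPM in UCPRP and 11.54 ± 11.7 CPM in UCS, Cxcl5 at 32.66 ± 6.48 and 38.8 ± 13.4 CPM, and Krt13, a keratin of conjunctiva, at 9317 ± 1400 and 9742 ± 1180 CPM. Muc5ac had a lower mean in UCPRP (213.5 ± 78 against 374.7 ± 114 CPM), as had Gp2 (106.4 ± 32.1 against 173.2 ± 64.4 CPM) and Ltf (300.2 ± 92.7 against 541.6 ± 254 CPM), none of them past the test. The genes ranked first were Otp, a homeobox gene (3 counts in UCPRP, 56 in UCS; ratio 18.9, interval 6.13 to 94.2), Avp (1 and 39 counts; ratio 39.4, interval 6.67 to 1600) and Cxcl14, a chemokine of epithelia (32.69 ± 7.36 against 17.08 ± 3.61 CPM), each with an edgeR adjusted p of 0.985. By edgeR 0 genes were called, with 393 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. With clock phase as a term edgeR called 0 genes (250 at an unadjusted p under 0.05) and camera called 15 lists. Of the nerve lists, axon growth genes were higher in UCPRP in 22 of 26 cases (median log2 fold change 0.42, none past the test, also adjusted over the list alone; camera adjusted p = 0.00104; adjusted p = 0.669 with an estimated correlation). That call was lost without UCS replicate 1 or UCPRP replicate 3 (adjusted p up to 0.324). Genes of the retina were higher beside them (median 0.66, camera adjusted p = 0.00255; adjusted p = 0.669 with an estimated correlation), a call lost without UCS replicate 1, UCPRP replicate 2 or UCPRP replicate 3 (adjusted p up to 0.229), and so were genes of the lens (0.99, 5.57e-06; adjusted p = 0.669 with an estimated correlation). No other nerve list was called in this comparison or in those of UCS or UCPRP with Vehicle: camera adjusted p values ran from 0.102 to 0.969.

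Over the 12 libraries the mean of the axon growth list followed that of the retina list (Pearson r = 0.948, permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman coefficient 0.965, permutation p = 2e-05). Adjusted over the 6 relations computed, these were 3e-05 and 6e-05. Without the 2 libraries farthest from the median of the retina list (Vehicle replicate 1 and Control replicate 2) r was 0.964, within groups it was 0.958, and within the 8 high-clock libraries it was 0.965. The 4 low-clock libraries were too few for a value. The sensory neuron list followed the retina list too (r = 0.987, Spearman coefficient 0.986, permutation p = 1e-05 for each; 0.994 without the same 2 libraries and 0.988 in the high-clock libraries). For axon guidance r was 0.108 (permutation p = 0.75) and the Spearman coefficient −0.021 (p = 0.96), for Schwann cell and myelin genes r was −0.499 (permutation p = 0.099) and the Spearman coefficient −0.552 (p = 0.067), and for neurotrophic genes r was 0.057 (permutation p = 0.86) and the Spearman coefficient −0.196 (p = 0.54). The lens list and the axon growth list had r = 0.418 (permutation p = 0.18) and Spearman coefficient 0.371 (p = 0.24). Adjusted over the 6 relations, these 4 values of r had p values of 0.86, 0.2, 0.86 and 0.27, and those of the Spearman coefficient 0.96, 0.13, 0.65 and 0.36. Without the 2 farthest libraries (UCS replicates 1 and 3 for the lens list) r was −0.165, −0.701, −0.4 and 0.424, and within the high-clock libraries 0.549, −0.398, −0.299 and 0.137.

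**Figure D3:**
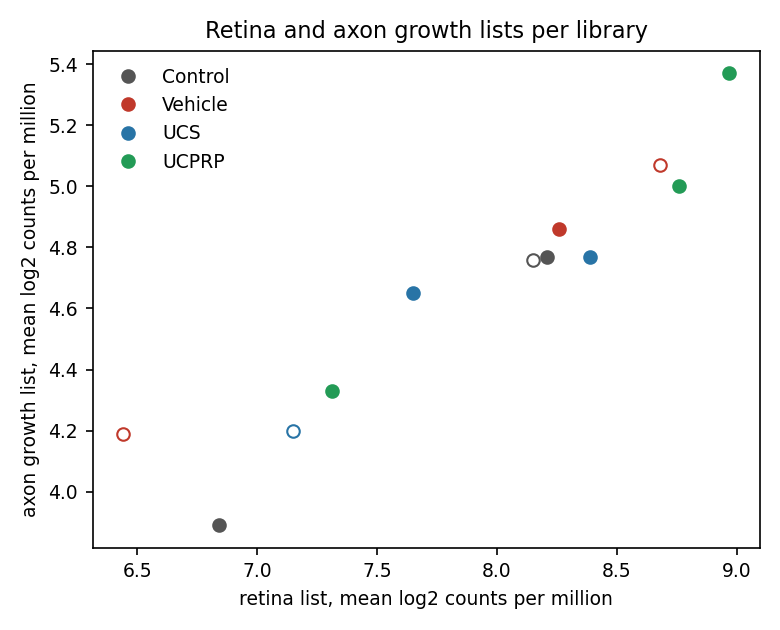
Mean of the axon growth list against mean of the retina list (both in log2 CPM) for each of the 12 libraries, coloured by group, with open symbols for low-clock libraries. The points rise together in each group, with r = 0.948 over the 12 libraries.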

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

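Of the tests weighed in this part, those of conjunctiva, retina, lens and clock phase were chosen only after the result was seen. Those of epithelial cell number, and the splits, were set before. That of other tissue was written before its result was seen, but its covariates were chosen after the data were seen.

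UCPRP and UCS, given with the same injury, differed in the median log2 fold change of 20 gene lists while no single gene passed over all genes (adjusted over the list alone, 1 chemokine gene was higher and 1 lower), and each median is given here because camera called the list between these groups. Lower in UCPRP than in UCS were inflammatory cytokines (−0.25), chemokines (−0.40), macrophage genes (−0.26), T and NK cell genes (−0.89), MHC class II and dendritic cell genes (−0.46), interferon-stimulated genes (−0.28), complement (−0.14), corneal epithelium (−0.03, though its mean was 0.12), conjunctiva and goblet cell genes (−0.20), cell cycle (−0.14), cell death (−0.33), junctions (−0.19), cholesterol synthesis (−0.26), iris and melanocyte genes (−0.16) and Y-linked genes (−0.14). Higher were matrix (0.14), axon growth (0.42), lens (0.99), retina (0.66) and immediate early genes (0.29). The difference was tested by camera with its preset correlation, and with an estimated correlation it held for none of the 20 (adjusted p = 0.778 with an estimated correlation for cell cycle and 0.669 for each of the others). The T and NK cell list lost its call without UCS replicate 3 (camera adjusted p = 0.104), as did the macrophage list (0.067) and the cell death list (0.067), and the MHC class II list turned direction (0.749). Of the 12 fits with 1 library left out, the call was lost in 9 for complement and for iris and melanocyte genes, 6 for corneal epithelium and for matrix, 5 for inflammatory cytokines and for goblet cell genes, 3 for chemokines, cell cycle and retina, 2 for axon growth and Y-linked genes, and 1 for junctions. With RLE scaling complement, corneal epithelium and iris and melanocyte genes (0.0606 each) and inflammatory cytokines (0.0598) also lost it. With clock phase as a term 15 lists were called, and matrix (0.62), inflammatory cytokines (0.595), cell cycle (0.565), chemokines (0.118) and goblet cell genes (0.0838) were not; the difference in the inflammatory list mean was −0.16 (SE 0.33) without the term and 0 (SE 0.28) with it. The lists of cholesterol synthesis, interferon-stimulated genes, lens and immediate early genes kept theirs in all 12. For lens this does not show a steady difference between the groups. Its list mean was 0.24, 6.99 and 0.63 in the UCS libraries and 5.15, 2.73 and 7.4 in the UCPRP libraries (SD 3.79 and 2.34).

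The loss of Krt12 and the gain of goblet cell genes after injury could come from more conjunctiva in the injured samples. For Krt12 the keratocyte genes argue only against whole conjunctiva in place of nearly all cornea, which would take genes restricted to corneal keratocytes down as far. Their median log2 fold change was −0.06 (median absolute deviation 0.43, genes from −1.45 for Kera to 1.05 for Lum). Whether the listed genes are also expressed in conjunctival stroma was not tested. Conjunctival epithelium over a kept corneal stroma would leave these genes unchanged, so for Krt12 that stays open. For the goblet cell genes more conjunctiva stays open as well. Of the keratins of conjunctiva, Krt4 rose by 2.30 (SE 0.33), as far as the explanation asks, and Krt13 by 1.63 (SE 0.28), less than it asks. Conjunctival tissue, conjunctival cells growing over the cornea and a changed state of corneal cells cannot be told apart by these keratins. An equal loss of all epithelial cells is excluded as the whole cause of the keratin loss. The 8 genes of any epithelium had a median of −0.48 (median absolute deviation 0.63). They cannot test a loss limited to the cells that carry Krt12, with other epithelial cells kept or in their place. Of these 8 genes, 2 were called higher, Krt14 (2.68) and Epcam (0.71). Another 4 were called lower, Krt5 (−1.26), Jup (−1.02) and Perp (−0.99) among them. Sections stained for Krt12, Krt13 and Muc5ac would show whether such cells lie on the cornea. They would not separate overgrowth by conjunctival cells from a changed state of corneal cells.

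The higher axon growth genes in UCPRP than in UCS could come from retinal RNA, and the values this needs are there. The difference in the list mean was 0.36 (SE 0.37) without a covariate and 0.06 (SE 0.12) with the retina list as one, with a slope of 0.49 (SE 0.05). The difference without a covariate lies within its own standard error, so there is little for any cause to account for. With the lens list as covariate it was 0.16 (SE 0.38), so lens RNA cannot be told apart from no contribution. Corneas dissected free of posterior tissue would give the test.

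The lower inflammatory genes in both treated groups could come from clock phase, since Vehicle held 1 of the 8 high-clock libraries. The list mean differed from Vehicle by −0.65 in UCS and −0.81 in UCPRP (SE 0.33 each), and with phase as a term by −0.48 (SE 0.28) and −0.48 (SE 0.31), so phase cannot be told apart from treatment as the source of part of it. For the macrophage list, treated minus Vehicle was −0.66 (SE 0.23) with the term and −0.66 (SE 0.19) without. A phase effect equal in all groups thus did not lessen this difference. Within the high-clock libraries the list mean was 4.67 in Vehicle, 4.42 and 4.85 in UCS, and 4.2, 4.11 and 4.24 in UCPRP. In the low-clock ones it was 5.25 and 5.03 in Vehicle and 4.12 in UCS. UCPRP had no low-clock library, so a phase effect particular to injured corneas cannot be told apart from treatment. With the retina, lens and muscle lists as covariates the inflammatory difference was −0.82 (SE 0.32, 5 residual degrees of freedom), against −0.73 (SE 0.28) without. RNA of these tissues thus did not lessen it. With so few degrees of freedom, and without conjunctiva as a covariate, other tissue is not excluded as a cause. Groups harvested at 1 time of day, with more pools, would give the test.

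Each comparison was set beside the 10 ways to split its 6 libraries into groups of 3, which are too few to give a share under 0.05. The other splits mix the groups unevenly and keep part of any real difference, so they do not show what no difference would give. In the comparisons with Control they also put the injury difference into the spread within groups, which by itself lowers the gene calls. For genes, the real split gave 2661 (Vehicle with Control), 1753 (UCS with Control) and 1671 (UCPRP with Control) calls and the highest other split gave 0, so 1 of 10 splits reached the real value in each. For UCS with Vehicle the real value was 0, which all 10 reach. The highest other was 72, in the split of Vehicle replicates 1 and 2 with UCS replicate 3 against the rest. That split keeps Vehicle replicates 1 and 2 together, and the cause of its calls was not tested. For UCPRP with Vehicle and UCPRP with UCS the real and the highest other value were 0, so all 10 reach it.

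For lists, the real values and the highest others were 18 and 20 (Vehicle with Control), 16 and 19 (UCS with Vehicle), 20 and 21 (UCPRP with Vehicle), 20 and 21 (UCPRP with UCS), 18 and 20 (UCS with Control), and 15 and 18 (UCPRP with Control), with 4, 5, 2, 2, 2 and 4 of 10 splits as large as the real one. In Vehicle with Control the split that gave 20 follows clock phase, and in UCS with Vehicle the split that follows it gave 16, the same as the real one. The reversal share was set beside 20 assignments of the 6 injured libraries, also too few for a share under 0.05: 79.3% for UCS with 80.8% as the highest other (3 of 20 as high), and 81.5% for UCPRP with 77.3% as the highest other (1 of 20).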

How the results depend on the processing

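No call of a named gene reversed under the 20 settings run for named genes (8 alternatives and 12 fits with 1 library left out); the other alternatives were read for counts of calls only. The alternatives labelled by clock phase and by other tissue were chosen only after the data were seen. Where a cause is not given, the cause was not tested.

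Vehicle with Control: against 1545 higher and 1116 lower genes there were 393 and 181 in the high-clock libraries only and 129 and 25 in the low-clock libraries only (fewer libraries), 917 and 389 at a log2 fold change of at least 1 (a stricter limit), and 604 lower with only these 2 groups fitted (fewer libraries). UCS with Vehicle went from 0 to 2 higher and 11 lower with DESeq2, and UCPRP with Vehicle from 0 to 6 and 139. UCS with Control (1032 and 721) gave 604 and 423 in the high-clock libraries, 0 and 0 in the low-clock libraries (1 residual degree of freedom), 608 and 293 at a log2 fold change of at least 1, and 1103 lower with the retina list as covariate. UCPRP with Control (854 and 817) gave 474 and 535 in the high-clock libraries, 459 and 332 at a log2 fold change of at least 1, and 532 lower with only these 2 groups. No fit within the low-clock libraries was possible for UCPRP, which has none. Other scaling moved the share of higher calls by less than 10 points.

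Lists called fell to 0 with an estimated correlation in all 6 comparisons, and with fry to 0 in UCS with Vehicle, UCPRP with Vehicle and UCPRP with UCS and to 9 in UCS with Control. The reversal share of 79.3% for UCS was 67.8% over all genes and 65.7%, 82.4% and 66.8% with Vehicle replicate 1, 2 or 3 for the injury change; that of 81.5% for UCPRP was 64.2% over all genes and 84.9% and 70% with Vehicle replicate 1 or 3. The simulated share over all genes was 59.4% with a real injury and no treatment effect and 66.8% with all groups unchanged, near the 67.8% of UCS and above the 64.2% of UCPRP, so the shares over all genes are not read as reversal.

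With 1 library left out, Vehicle with Control gave 1135 to 1518 higher and 626 (without Vehicle replicate 2) to 1118 lower genes. UCS with Vehicle gave 0 to 2 higher and 0 to 35 lower and UCPRP with Vehicle 0 to 19 and 0 to 176, above 0 only without Vehicle replicate 3, after which that group holds low-clock libraries alone. UCPRP with UCS stayed at 0. UCS with Control gave 655 (without Control replicate 1; 662 without UCS replicate 3) to 1088 higher and 427 (without UCS replicate 3; 445 without UCS replicate 2) to 718 lower. UCPRP with Control gave 513 (without Control replicate 1; 517 without UCPRP replicate 3; 559 without UCPRP replicate 2) to 896 higher and 450 (without UCPRP replicate 2; 481 without UCPRP replicate 3) to 860 lower. Lists called ran from 16 to 21, 13 to 19, 17 to 22, 9 (without UCS replicate 3; 11 without UCPRP replicate 3; 12 without Control replicate 2) to 22, 16 to 19 and 13 to 18 in the order Vehicle with Control, UCS with Vehicle, UCPRP with Vehicle, UCPRP with UCS, UCS with Control, UCPRP with Control. Reversal ran from 74.4% to 83.7% and from 79.5% to 86.6%.

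With a replicate block there were 1376 and 924, 0, 0, 0, 882 and 611, and 717 and 685 genes and 19, 16, 20, 19, 19 and 14 lists in the same order. Over 18 pairs of libraries with the same number the correlation of deviations averaged −0.024 (−0.581 to 0.494) against 0.014 for others, and 3 of 12 libraries correlated best with their own number, so the numbers gave no sign of pairing.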

Other observations

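Part of the cell death list rose with the injury. The inflammasome genes Nlrp3 and Casp1 rose in Vehicle against Control with log2 fold changes of 4.60 and 2.48, the gasdermin gene Gsdma with 2.76 and the p53 target Pmaip1 with 2.44 (edgeR adjusted p = 0.00112, 0.000328, 0.000935 and 0.00191), and 8 of 20 genes of the cell death list rose, or 10 adjusted over the list alone (camera adjusted p = 1.58e-05; adjusted p = 0.326 with an estimated correlation). Of the oxidative stress list 5 of 20 rose and 3 fell, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.825), with Hmox1, which breaks down haem, at 1.59 and Gsr, which reduces glutathione, at 1.12. In the WNT and BMP list Id2 (−1.42), the WNT inhibitor Dkk1 (−1.39) and the WNT receptor Fzd6 (−0.98) were among 5 of 25 genes that fell while 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0191; adjusted p = 0.622 with an estimated correlation). That call was lost without Control replicate 2 or Vehicle replicate 2 (adjusted p up to 0.133). Kit, the receptor of mast cells and melanocytes, fell from 114.4 ± 7.62 to 34.38 ± 10.5 CPM (edgeR adjusted p = 0.00128) and Hdc, which makes histamine, rose from 2.848 ± 1.03 to 36.89 ± 26.9 CPM (edgeR adjusted p = 0.0044; not called by limma-voom), so the mast cell list had 1 of 6 each way, also adjusted over the list alone (camera adjusted p = 0.68).

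Cholesterol synthesis genes were lower in the injured corneas, and most so with UCPRP. Against Control 9 of 17 fell in UCPRP and 3 in each of Vehicle and UCS, or 12, 3 and 5 adjusted over the list alone, with Insig1 at −1.04, −1.09 and −0.92 (camera adjusted p = 5.43e-09, 0.00162 and 0.00108; adjusted p = 0.467, 0.622 and 0.685 with an estimated correlation). The list was also lower in UCPRP than in Vehicle (camera adjusted p = 3.27e-05; adjusted p = 0.554 with an estimated correlation) and than in UCS (camera adjusted p = 2.23e-09; adjusted p = 0.669 with an estimated correlation), with no gene past the test. With clock phase as a term the camera adjusted p of the list was 0.0145 for UCPRP with Vehicle and 9.81e-08 for UCPRP with UCS. Its mean was 7.08, 6.93 and 6.92 in the UCPRP libraries, all high-clock. In Vehicle it was 7.01 in the high-clock library and 7.44 and 7.2 in the low-clock ones. Genes higher against Control in UCPRP included Cxcl14 (1.04), the complement protease C1s1 (1.12) and the matrix gene Postn (1.37).

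Values for other lists in Vehicle against Control follow, with the same counts adjusted over each list alone. No gene passed among 25 of the cell cycle (camera adjusted p = 0.125; Mki67 0.23), 14 of retina (0.991), 18 of lens (0.274; Cryaa −1.27), 4 Y-linked (0.604; Eif2s3y −0.31) or 6 histone genes (0.87; mean 0.03, median 0.10, direction of the test down). Of 15 circadian genes 1 fell (Hlf, −1.39; camera adjusted p = 0.0954), of 5 red blood cell genes 1 fell (camera adjusted p = 0.0217; adjusted p = 0.586 with an estimated correlation; lost without Control replicate 1, Control replicate 2 or Vehicle replicate 3, up to 0.086), and of 13 immediate early genes 1 rose and 1 fell (camera adjusted p = 0.791). Of 7 meibomian gland genes 2 rose (Cidea 1.76; camera adjusted p = 0.356), and 1 rose in each of the adipocyte list of 3 (camera adjusted p = 0.254) and the iris and melanocyte list of 8 (camera adjusted p = 0.738; median −0.19).

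Lists called between treated groups and Vehicle, and not described above, held no gene past the test over all genes; adjusted over the list alone, 3 limbal and 3 goblet cell genes passed in UCPRP. In UCS the T and NK cell list was higher (camera adjusted p = 0.0377; adjusted p = 0.75 with an estimated correlation) and turned lower without UCS replicate 3 (0.275), and the call was lost without Control replicate 2 or any of the 3 Vehicle replicates (T and NK cell list, up to 0.09). The keratinization (0.0377; adjusted p = 0.719 with an estimated correlation), interferon-stimulated (0.0407; adjusted p = 0.75 with an estimated correlation) and lens (0.000628; adjusted p = 0.75 with an estimated correlation) lists were lower, each lost without at least 3 of the libraries in turn (up to 0.297, 0.636 and 0.691). In UCPRP the MHC class II list (camera adjusted p = 0.00288; adjusted p = 0.619 with an estimated correlation) was lower whichever library was left out. The limbal (0.018; 0.467 with an estimated correlation), T and NK cell (0.0409; 0.768 with an estimated correlation), keratinization (0.0422; 0.619 with an estimated correlation) and goblet cell (0.0496; 0.663 with an estimated correlation) lists were lower and the retina list (0.0353; 0.79 with an estimated correlation) higher, each lost without 2 or more of the libraries in turn (up to 0.0713, 0.415, 0.299, 0.267 and 0.411). The retina list turned lower without Vehicle replicate 1 (0.473) and lost its call with clock phase as a term (0.173), as did the goblet cell (0.147) and keratinization (0.0548) lists in UCPRP and the keratinization (0.0722) and T and NK cell (0.0823) lists in UCS.

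Other lists stayed changed against Control in both treated groups, given here for UCS and then UCPRP. Matrix genes rose in 7 and 10 of 23 cases and 1 fell in each (10 and 14 rose adjusted over the list alone; camera adjusted p = 2.59e-05 and 1.08e-06; adjusted p = 0.536 and 0.452 with an estimated correlation), and proteases rose in 10 of 21 cases in each (11 adjusted over the list alone; camera adjusted p = 2.6e-05 and 0.000191; adjusted p = 0.333 and 0.402 with an estimated correlation). Complement genes rose in 8 and 6 of 15 cases (11 and 8 adjusted over the list alone; camera adjusted p = 7.22e-08 and 9.02e-06; adjusted p = 0.212 and 0.389 with an estimated correlation), and MHC class II and dendritic cell genes in 13 and 4 of 17 (14 and 6 adjusted over the list alone; camera adjusted p = 7.03e-09 and 7.85e-06; adjusted p = 0.457 and 0.515 with an estimated correlation). Chemokines rose in 8 and 5 of 26 cases (12 and 6 adjusted over the list alone; camera adjusted p = 8.57e-06 and 0.00113; adjusted p = 0.471 and 0.604 with an estimated correlation). Junction genes fell in 5 of 20 cases in each (6 and 10 adjusted over the list alone; camera adjusted p = 0.00224 and 2.34e-06; adjusted p = 0.685 and 0.515 with an estimated correlation), a call lost in UCS without Control replicate 2 (adjusted p = 0.0795).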
